A study of Mus musculus with 6 samples.

How the data were processed

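Gene expression was measured by bulk RNA sequencing of mouse temporomandibular joint (TMJ) tissue in 6 libraries, 3 labelled Igf2bp2 knockout (KO) and 3 labelled wild type (WT), from mice of 10 weeks that the series describes as littermates. Per the labels' protocols, RNA was extracted with TRIzol and poly(A) RNA was isolated with a bead kit before library preparation. The submitters' processing notes name HISAT2 2.1.0, StringTie 2.1.5 and the mouse build mm39. The role of each tool, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The authors deposited 1 table of raw read counts per gene symbol, with 22032 genes and 1 column per library, not normalized. Every listed gene had a count above 0 in at least 1 library. The reference held here is another build, so no coordinates are printed, and its transcripts were used only for the length of the longest transcript of each symbol. Members of gene families with near-identical copies are uncertain, since the rule for shared reads is not known, and reads of overlapping antisense genes cannot be told apart.

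Total counts ranged from 28551236 to 35094127 per library. Mitochondrial genes took 85.3% to 90.8% of them, which left 2625472 to 4899680 counts on nuclear genes. Genes at 2 counts outnumbered genes at 1 count by 4.69 to 5.06 times in each library, so both mates of a read pair appear to have been counted. Counting intervals and floors cover counting error only, because the libraries carry no molecular identifiers.

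Groups and replicate numbers were taken from the sample titles. All 6 libraries were to be tested as separate samples, a plan fixed before the data were examined together with the main test, the other settings to try, 37 gene lists and the rule for named genes. The libraries of each group were compared first. For each pair, the variance between libraries of every nuclear gene with at least 20 summed counts was divided by the variance that random sampling of read pairs gives, with 2 counts per pair. KO 1 and KO 3 had a median ratio of 0.94 and WT 2 and WT 3 of 0.96, while the other pairs within a group had medians of 1.31 to 1.63. Each of those close pairs was therefore summed and counted as 1 sample, which gave n = 2 samples per group (KO 1+3, KO 2, WT 1 and WT 2+3). This departs from the plan. The limit of 1.1 on the median ratio was set after the ratios had been seen, and the number of differing genes had by then been seen under both treatments, so the result with 6 separate libraries (3452 genes) is given beside the main one (2580 genes). The labels do not say that libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

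The main test was edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with a minimum count of 10, scaled by trimmed mean of M-values (TMM), and fitted with the robust quasi-likelihood model with group as the term. Genes with a Benjamini-Hochberg false discovery rate (FDR) under 0.05 were called. Expression is given as CPM, the count scaled to library size, with TMM factors, as mean ± SD over the 2 samples of a group. Log2 fold changes are KO minus WT. Their standard error (SE) was derived as the absolute change divided by the square root of the F statistic, and 95% intervals rest on it. Gene lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 35 lists tested. The same test with an estimated correlation, which has little power with 2 samples per group, is given beside it, and fry where its call differs. For a gene with no count in a group, the fold is given against a floor of 3 counts over that group. A read pair appears to give 2 counts, so the floor is under 2 pairs and the fold is not a strict lower bound.

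Genes are named by a fixed rule. It takes Igf2bp2, its paralogs Igf2bp1 and Igf2bp3, and Fos, Pparg and Nfatc1. It adds the 12 higher and 12 lower genes of largest change among those that passed, did not overlap between groups over the 6 libraries and had a mean of at least 1 CPM, leaving out models without a name. From each list described it takes up to 4 members of smallest p and, for cell types, the most abundant member, and it takes the 5 most abundant genes. Ddx3y, Xist and the genes named only among the additional observations, Arntl, Usp2, Wee1 and Mmp20 included, were chosen outside the rule. Others outside it are said to be so, and some genes that it takes are not reported here.

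Other settings fixed beforehand were DESeq2 size factors, upper-quartile factors, no filter, a filter of at least 50 counts in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, a minimum log2 fold change of 1, leaving out each library, the replicate number as a block, library sizes without muscle, erythroid and mitochondrial genes, and the fast muscle list as a covariate. Added after seeing the data were a block for KO 2 and WT 1 against the rest and counts halved to read pairs, and the planned 6 separate libraries became an alternative. The code was tested on simulated counts for 14632 genes with 2 samples per group and 200 changed genes. It recovered 62% of changes of 1 and 91.8% of changes of 2 on the log2 scale, and 2.56% of its calls were false. The simulated spread was the one fitted to these samples, so these shares test the code only. They do not give the share of false calls where animals vary more. Libraries simulated from the same RNA had a median variance ratio of 0.978, and a 10% variation between animals gave 5.85 in genes of 1000 to 5000 summed counts.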

Results

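Poly(A) RNA of the temporomandibular joint, the joint between the mandible and the temporal bone, was sequenced from Igf2bp2 knockout and wild-type mice aged 10 weeks. IGF2BP2 is an RNA-binding protein that reads m6A marks on mRNA. The series title links it to bone loss beneath the joint cartilage and to a network of FOS, PPARγ and NFATC1, so the comparison of KO with WT asks how expression in the joint differs without it. Each group had 3 libraries. Total counts were 32166712, 35094127 and 31813171 in KO 1 to 3 and 33935022, 28551236 and 32441355 in WT 1 to 3. The mitochondrial transcripts COX1, CYTB, ND1, ND4 and COX2 were the most abundant genes, and COX1 alone took 30.5% of all counts. Mitochondrial genes took 85.8% ± 0.386 of the counts in KO and 90.7% ± 0.191 in WT (SD, n = 2 samples per group), and 12 of the 13 mitochondrial genes were lower in KO by edgeR's quasi-likelihood test. COX1 differed by -0.64 (FDR 0.00199), and its call was lost without KO 2 (FDR 0.141), as were those of CYTB, ND1, ND4 and COX2 (FDR 0.143, 0.146, 0.16 and 0.217). Nuclear genes held 4604575 to 4899680 counts in KO and 2625472 to 3205190 in WT. The changes of mitochondrial genes are relative to them, as COX1 had 29364482 counts over KO and 29812424 over WT. TMM factors were 1.22 and 1.20 in the KO samples and 0.862 and 0.794 in the WT samples. Lower mitochondrial and higher nuclear transcripts thus cannot be told apart. The Y-linked gene Ddx3y had 199 to 468 counts in each library, and Xist had at most 4.

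The libraries of a group were not equally far apart. KO 1 and KO 3 differed by less than the sampling noise of read pairs in the median gene (ratio of observed to counting variance 0.94), as did WT 2 and WT 3 (0.96), and each of these pairs was counted as 1 sample. In genes of 1000 to 5000 summed counts the ratios were 0.98 and 1.05 for these pairs and 2.43 to 5.62 for the others within a group. The mean ratios over all genes were 1.18 and 1.08, so some genes differed by more than counting noise.

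**Figure D1:**
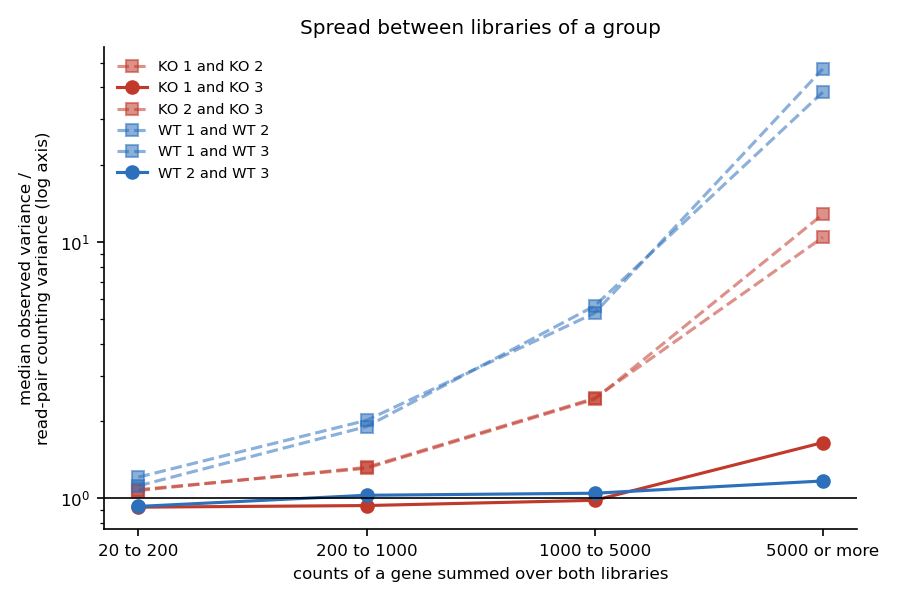
Median ratio of observed to read-pair counting variance (log axis) between libraries of the same group, by the summed counts of a gene. Solid lines show KO 1 with KO 3 and WT 2 with WT 3, which stay at 0.92 to 1.65, while the dashed lines of the other pairs reach 10.4 to 47.2 in the most abundant genes.

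Igf2bp2 was lower in the KO libraries, with 13, 14 and 10 counts in KO 1 to 3 and 38, 20 and 24 in WT 1 to 3. Its level was 0.314 ± 0.027 CPM in KO and 1.10 ± 0.277 CPM in WT (SD, n = 2), a log2 fold change of -1.80 (SE 0.39, edgeR FDR 0.00589). KO libraries thus kept some counts of the gene, and the part of it that is deleted is not given in the sources used here. Over the alternatives the FDR ranged from 0.00036 to 0.544, and the DESeq2 Wald test put it at 0.0557. The paralogs Igf2bp1 and Igf2bp3 had too few counts to test, with at most 2 and 7 in a library.

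Of the 3 genes in the title, Fos and Pparg were lower in KO and Nfatc1 did not pass. Fos, an AP-1 transcription factor induced by stimulation, had 0.838 ± 0.262 CPM in KO and 2.58 ± 0.702 in WT, a log2 fold change of -1.65 (SE 0.29, edgeR FDR 0.0015). Pparg, the nuclear receptor that drives adipocyte differentiation, had 2.11 ± 0.0136 CPM in KO and 3.59 ± 0.144 in WT, a change of -0.77 (SE 0.18, FDR 0.00994). Nfatc1, the master transcription factor of osteoclasts, had 6.92 ± 0.586 CPM in KO and 6.52 ± 1.33 in WT, with a difference of 0.10 (95% interval -0.25 to 0.44, FDR 0.752). Adjusted over the list alone, Fos had 0.000256, Pparg 0.00149 and Nfatc1 0.561. Tested together, the 3 genes were not called (camera adjusted p = 0.118, and 0.658 with an estimated correlation). In the same libraries 7 of 19 immediate-early and AP-1 genes, Fos included, were lower and 3 higher. Of 12 white adipocyte genes 6 were lower and 4 higher. Whether the changes of Fos and Pparg are separate from these shifts was not tested. The Pparg call was lost without KO 2 (FDR 0.0826) and in the DESeq2 Wald test (FDR 0.157). With the fast muscle list as a covariate, which leaves 1 residual degree of freedom, Igf2bp2, Fos and Pparg did not pass and Nfatc1 passed as higher (0.74, FDR 0.0498).

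**Figure D2:**
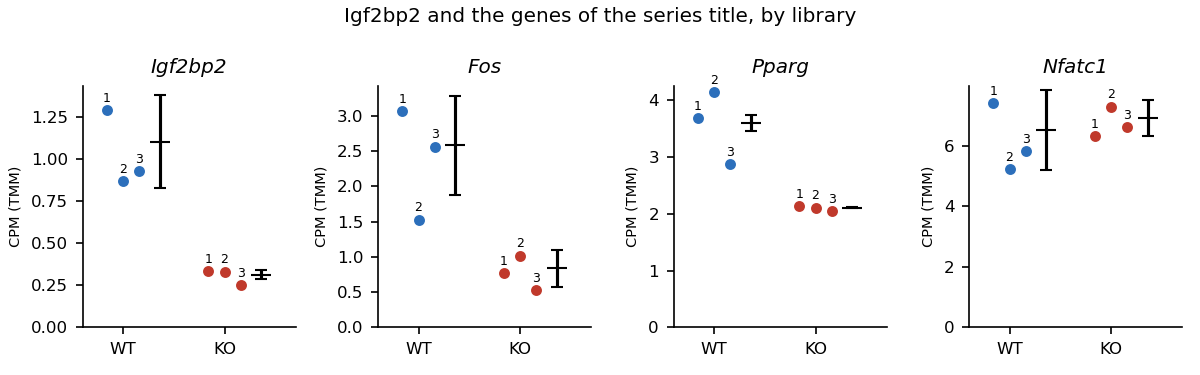
CPM (TMM-scaled) of Igf2bp2, Fos, Pparg and Nfatc1 in each of the 6 libraries, numbered by replicate, with the mean and SD of the 2 samples per group in black. The KO libraries lie below all WT libraries for Igf2bp2, Fos and Pparg, and the groups overlap for Nfatc1.

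Across the transcriptome, 2580 of 14632 tested genes differed between KO and WT, 1339 higher and 1241 lower in KO (edgeR, FDR 0.05). The 12 genes named for the largest increase included neuronal and secretory ones. Htr3a, a serotonin receptor subunit, Dbh, the enzyme that makes noradrenaline, Slc5a7, the choline transporter, and Chrna3, a nicotinic receptor subunit, had 465, 417, 347 and 274 counts over the KO libraries and none in WT. That makes them 100.2-fold, 89.9-fold, 74.8-fold and 59.1-fold higher against a floor of 3 counts over the WT group. As a read pair appears to give 2 counts, these are not strict lower bounds. The neuropeptide gene Vip had 3707 counts in KO and 4 in WT, all in WT 3. The salivary secretory genes Smr3a and Dcpp1 rose by 6.70 and 6.49 on the log2 scale, and Smr3a, with 23, 9 and 5 counts in WT 1 to 3, by 7.46 without WT 1. The secretoglobin Scgb2b27 rose by 5.45 and the neuronal noncoding RNA Snhg11 by 5.43, or 6.27 without WT 3. Duox2, an oxidase that makes hydrogen peroxide, had 479 counts in KO and 4 in WT, all in WT 1. Scgb1b27 had 322 counts in KO and 5 in WT, and the imprinted gene Rtl1 478 and 10, all WT counts of both in WT 3. Rtl1 has an antisense partner whose reads cannot be separated without the strand setting.

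The 12 genes named for the largest decrease included olfactory and secretory genes, clock genes and an AP-1 gene. Gfy, a gene of olfactory neurons, was 15.2-fold lower, and the odorant-binding protein genes Obp2b, Obp1b and Obp2a were 15.2-fold, 13.7-fold and 11.4-fold lower in KO. Akap5, a kinase anchoring protein, was 13.2-fold lower and Reg3g, an antimicrobial lectin, 10.8-fold lower. Fosb fell by 3.14 on the log2 scale, and the clock genes Nr1d1 and Dbp fell by 3.03 and 2.88. Bpifb4, Dmbt1 and Mup4 had log2 fold changes of -3.08, -2.95 and -2.95. Reads of the Dcpp, secretoglobin, Obp and Mup genes may be shared with near-identical family members, so the split within each family is uncertain.

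All 2580 calls had the same sign in KO 2 against WT 1 as in KO 1+3 against WT 2+3. A call from these same samples largely requires that, so it is no separate support for the calls. For 2551 of them the 3 KO libraries did not overlap the 3 WT libraries, which held for 5616 of all 14632 tested genes. An absolute log2 fold change of at least 1 was reached by 575 higher and 483 lower genes. With the 6 libraries as separate samples, as first planned, 3452 genes differed (1745 higher and 1707 lower), 2475 of them shared with the 2580. Without KO 2 the count was 1149, with the DESeq2 Wald test 1371.

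Of the 35 lists tested, 16 were called by camera at the preset correlation, 6 higher and 10 lower in KO. None was called with an estimated correlation, where the lowest adjusted p was 0.442. With 2 samples per group that setting has little power. Even the salivary gland list, with all 13 tested members higher, reached no lower value, so that setting decides little about any list. By fry 10 lists moved on balance in 1 direction, and 31 held genes changing in either direction.

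Salivary gland genes had the largest median change of the lists tested. All 13 tested members rose in KO, also when adjusted over the list alone (camera adjusted p = 4.16e-92, and 0.442 with an estimated correlation), with a median log2 fold change of 3.65, or 3.60 with the member absent from WT set at its bound. Bpifa2, a major secretory protein of the parotid, had 266 ± 4.61 CPM in KO and 21.2 ± 0.226 in WT. Dcpp3 was 16.2-fold and Car6, a carbonic anhydrase secreted into saliva, 9.47-fold higher.

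All 13 Schwann cell and nerve genes changed, in both directions. The 9 that fell belong to Schwann cells and myelin, among them Prx, which stabilises the myelin sheath (25.8 ± 2.59 CPM in KO and 73.8 ± 0.0408 in WT, log2 fold change -1.52), and S100b (-1.39). The 4 that rose encode neuronal filaments: Prph rose by 3.80, and Nefl, Nefh and Nefm, named after their values were seen, by 2.45, 3.33 and 2.54. Nefh was at 4.35 without WT 2, and Nefm at 1.86 without WT 1 and 3.19 without WT 3. The call of Nefm, the weakest of the 4, was lost without KO 2, KO 3, WT 1 or WT 2 (FDR 0.143, 0.0663, 0.121 and 0.0554). The list was called lower (camera adjusted p = 5.83e-05, and 0.443 with an estimated correlation), with a median of -0.96 but a mean of 0.04. The counts adjusted over the list alone were also 9 lower and 4 higher.

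The circadian clock list was called lower (camera adjusted p = 2.33e-06, and 0.443 with an estimated correlation). It had 8 members lower and 4 higher of 15, and 8 and 5 adjusted over the list alone. Dbp, a clock output factor, fell from 34.0 ± 0.498 CPM in WT to 4.67 ± 0.937 in KO, and Nr1d1, which represses Bmal1, from 16.4 ± 3.92 to 1.99 ± 0.0241. Hlf and Bhlhe41 had log2 fold changes of -1.85 and -1.78. The 4 higher members were Cry1, Per2, Npas2 and Clock, named after their values were seen, with changes of 0.42 to 2.22, the highest in Npas2, which was at 3.57 without WT 1. Without KO 2 none of these 4 passed (FDR 0.179 for Cry1, 0.393 for Per2, 0.247 for Npas2 and 0.245 for Clock). Per2 was also lost without WT 3 (FDR 0.0559), Npas2 without KO 1, WT 2 or WT 3 (FDR 0.103, 0.0743 and 0.0713), and Clock without KO 1, WT 1 or WT 3 (FDR 0.0869, 0.157 and 0.0549).

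Immediate-early and AP-1 genes were also called lower (camera adjusted p = 0.00247, and 0.443 with an estimated correlation), with 7 of 19 members lower and 3 higher, and 8 and 3 adjusted over the list alone. Egr1 was 3.81-fold, Fosb 8.81-fold, Nr4a2 2.80-fold and Nr4a1 2.16-fold lower in KO. Jun, named after its values were seen, had 13.7 CPM in KO and 14.9 in WT (FDR 0.545). Heat shock and stress genes were not called as a list (adjusted p = 0.353), but the chaperones Hspa1a and Hspa1b were 2.71-fold and 2.31-fold lower and Chac1, a target of the amino acid response, 4.18-fold higher. That list had 4 members lower and 1 higher, and 5 and 2 adjusted over the list alone.

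Members of the PPARG target and lipid storage list moved in both directions: 7 of 18 rose and 5 fell, with the same counts adjusted over the list alone. Camera called the list higher (adjusted p = 0.00193, and 0.443 with an estimated correlation), although the median was -0.00 and the mean 0.15. Pdk4, which limits glucose oxidation, had 115 ± 2.43 CPM in KO and 11.5 ± 0.0746 in WT. The lipid droplet gene Plin4 was 7.92-fold, the fatty acid transporter Cd36 2.65-fold and the lipase inhibitor Angptl4 2.76-fold higher in KO. Pdk4 and Angptl4 also belong to a list of 18 fasting and glucocorticoid genes, written after the main results were seen, of which 15 rose. In the same libraries 9 of 20 fast muscle genes rose. The adipocyte hormone gene Adipoq was 3.68-fold lower and Cfd, the adipokine adipsin, 2.78-fold lower, while Lpl and Thrsp were 2.59-fold and 2.06-fold higher. The white adipocyte list, which holds these last genes, had 4 members higher and 6 lower of 12 and was not called by camera (adjusted p = 0.356) but was called lower by fry (adjusted p = 0.0324). It had 4 and 7 adjusted over the list alone. Among brown adipocyte genes 3 of 10 were lower, with the same count adjusted over the list alone, and that list was not called by camera (adjusted p = 0.143). Ucp1, the uncoupling protein of brown fat, had 0.0256 ± 0.0362 CPM in KO and 0.697 ± 0.0794 in WT, a log2 fold change of -4.31. It rests on 4 KO counts, all in KO 3, against 53 in WT, and was at -3.69 without KO 2, while without KO 3 no KO count remains.

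**Figure D3:**
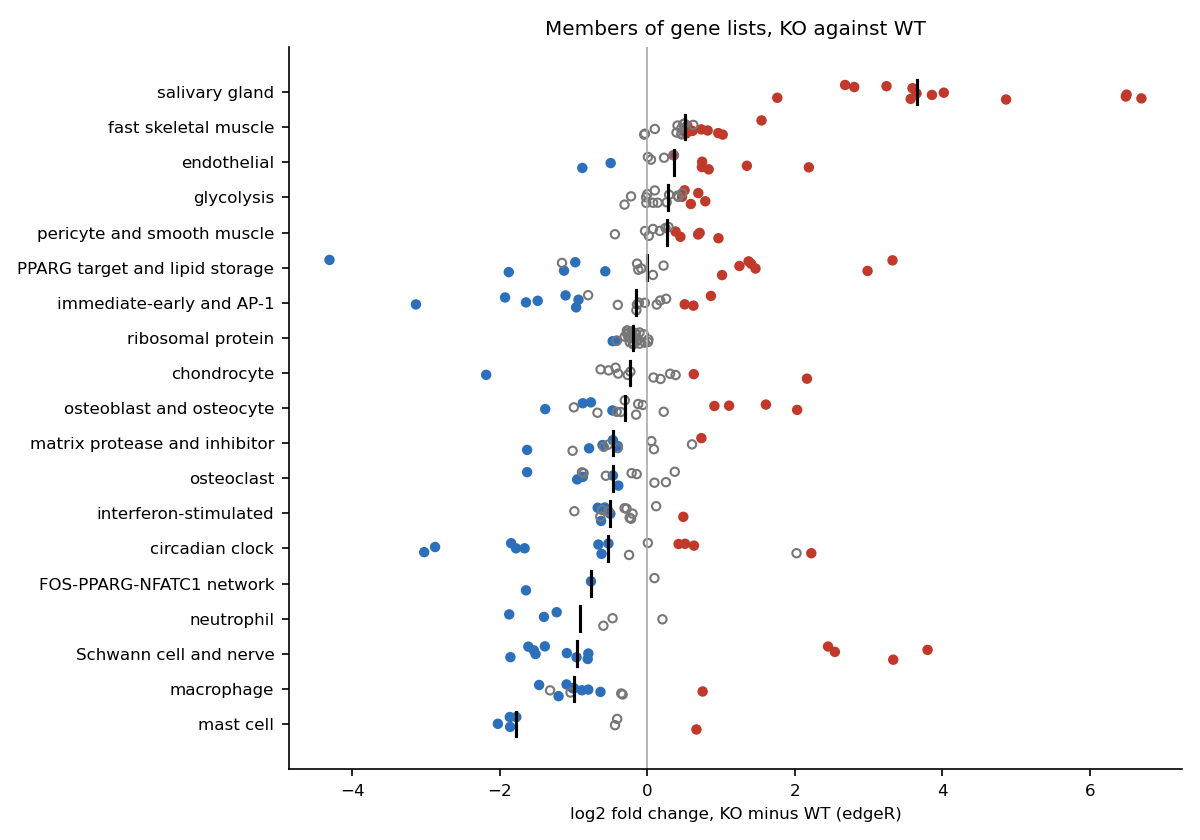
Log2 fold change (KO minus WT, edgeR) of each tested member of the 16 lists called by camera at the preset correlation and of 3 lists that were not called (FOS-PPARG-NFATC1 network, osteoblast and osteocyte, chondrocyte). Filled points passed the FDR of 0.05, red higher and blue lower in KO, open points did not, and bars mark medians, from -1.78 in the mast cell list to 3.65 in the salivary gland list.

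Among genes of bone cells, osteoclast genes were called lower in KO (camera adjusted p = 0.019, and 0.502 with an estimated correlation). Of 13 tested members 5 were lower and none higher by edgeR, and 6 lower and 1 higher adjusted over the list alone. The libraries are of joint tissue, so bone was not measured apart. Oscar, Ocstamp, Dcstamp, Calcr and Siglec15 of this list were not tested. Over all genes 8 tested members did not pass, among them Atp6v0d2 and Tcirg1 (FDR 0.264 and 0.481). These were named outside the rule. Mmp9, a collagen-degrading protease, was 3.10-fold lower. Acp5, the osteoclast phosphatase TRAP, had 4.11 ± 0.421 CPM in KO and 7.98 ± 0.308 in WT, a log2 fold change of -0.95 (SE 0.15, FDR 0.000455). Car2 (-0.88, FDR 0.00987) and Ckb (-0.39, FDR 0.0281) also passed, as did Ctsk, the main collagenase of osteoclasts, named after its values were seen (-0.47, FDR 0.0328). Without KO 2 the list was not called (adjusted p = 0.0515), and the FDR of Car2 was 0.117, of Ckb 0.377 and of Ctsk 0.37. Without WT 2 the FDR of Ctsk was 0.0809. In the same libraries 8 of 13 macrophage genes were lower and 1 higher.

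Osteoblast and osteocyte genes split evenly, with 4 of 17 higher and 4 lower, and 4 and 5 adjusted over the list alone (camera adjusted p = 0.987). Phex, a protease of osteocytes and odontoblasts, was 4.09-fold higher, Bglap, the gene of osteocalcin, 3.05-fold higher, and Col1a1 had 528 ± 48.0 CPM in KO and 245 ± 26.6 in WT. The dentin gene Dspp of odontoblasts was higher in the same libraries, with 118 CPM in KO and 8.97 in WT. Col1a2, named after its values were seen like Dspp, was lower (-0.48, FDR 0.0188), a call lost without KO 2 (FDR 0.271) or WT 1 (FDR 0.0509). Runx2, the transcription factor of osteoblast commitment, was 2.61-fold lower. Among osteoclast-regulating ligands and receptors Csf1r, the receptor of the macrophage growth factor, was 2.02-fold lower and Efnb2 1.86-fold higher, the only members of 11 to pass over all genes, with 2 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.954).

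Of the chondrocyte, synovial, tendon and matrix protease lists, camera called the last. Chondrocyte genes had 2 of 13 members higher and 1 lower, the same counts as adjusted over the list alone (camera adjusted p = 0.81). Col11a2 rose 4.48-fold and Col10a1, the collagen of hypertrophic chondrocytes, was 4.55-fold lower, on 37 counts in KO and 105 in WT. Col2a1 and Acan of the same list, named outside the rule, were low and did not pass. They had 1.47 and 0.927 CPM in WT, with log2 fold changes of -0.27 (FDR 0.603) and -0.43 (FDR 0.426). Cartilage was not measured apart, so the changes of Col11a2 and Col10a1 cannot be placed in it. Among synovial lining and fibroblast genes 3 of 12 rose and 3 fell, and 3 and 4 adjusted over the list alone (adjusted p = 0.759). Prg4, the joint lubricant lubricin, had 46.0 ± 4.78 CPM in KO and 11.3 ± 0.862 in WT, Htra4 was 4.00-fold higher and Clu 2.27-fold lower. Tendon and fibrocartilage genes had 2 higher and 2 lower of 12, and 2 and 3 adjusted over the list alone (adjusted p = 0.81), with Angptl7 2.12-fold higher and Scx, the tendon transcription factor, 3.54-fold lower. Matrix protease and inhibitor genes were called lower (adjusted p = 0.032, and 0.502 with an estimated correlation), with 5 of 13 lower and 1 higher, and 9 and 1 adjusted over the list alone. That list shares Mmp9 and Ctsk with the osteoclast list, and its higher member was the inhibitor Timp3 (1.66-fold).

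The fast skeletal muscle list was called higher in KO (camera adjusted p = 3.98e-06, and 0.548 with an estimated correlation) but not by fry (adjusted p = 0.139). Of its 20 members 9 rose over all genes and 15 adjusted over the list alone. The fast myosin gene Myh2 was 2.92-fold, the giant thin-filament gene Neb 2.03-fold and Ttn 1.95-fold higher. Ckm, the member of highest mean CPM over the 6 libraries, had 1178 ± 171 CPM in KO and 856 ± 238 in WT (FDR 0.137). The glycolysis list was called higher (adjusted p = 0.0387, and 0.548 with an estimated correlation) with 5 of 18 higher and 8 adjusted over the list alone, among them the muscle glucose transporter Slc2a4 at 1.61-fold. The glycolysis call was lost without WT 1 (adjusted p = 0.0572), with at least 50 counts in 3 libraries (0.0894) and by fry (0.116). In the slow skeletal muscle list 1 of 11 passed, Mybpc1 at 1.54-fold higher, also adjusted over the list alone (adjusted p = 0.81). In oxidative phosphorylation 1 of 27 passed over all genes and none adjusted over the list alone (adjusted p = 0.28).

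Endothelial genes were called higher (camera adjusted p = 0.00409, and 0.502 with an estimated correlation), with 6 of 12 higher and 2 lower, and 7 and 2 adjusted over the list alone. Flt1, a receptor of VEGF, was 2.55-fold and the tight junction gene Cldn5 4.56-fold higher, while Kdr, the main signalling receptor of VEGF, was 1.84-fold lower. The pericyte and smooth muscle list had 5 of 12 members higher, the same adjusted over the list alone, and was called higher (adjusted p = 0.0416, and 0.52 with an estimated correlation). Lmod1 was 1.95-fold higher, and without KO 2 the pericyte and smooth muscle list was not called (adjusted p = 0.0901).

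Several immune cell lists were called lower in KO. The macrophage list was called (camera adjusted p = 1.24e-05, and 0.548 with an estimated correlation) with 8 of 13 members lower and 1 higher, and 10 and 1 adjusted over the list alone. Fry did not call the macrophage (adjusted p = 0.079), mast cell (0.0522), neutrophil (0.112) or interferon-stimulated list (0.0838). Lyz2, the lysozyme of myeloid cells, had 22.9 ± 0.0114 CPM in KO and 42.5 ± 5.08 in WT, and Mrc1 and Folr2, markers of resident macrophages, were 2.30-fold and 2.77-fold lower. The mast cell list (adjusted p = 0.00442, and 0.548 with an estimated correlation) had 4 of 7 lower and 1 higher, the same adjusted over the list alone, and was not called with at least 50 counts in 3 libraries (adjusted p = 0.408). The mast cell proteases Mcpt4, Tpsb2 and Cma1 were 4.08-fold, 3.43-fold and 3.65-fold lower, and the transcription factor gene Gata2 1.59-fold higher. In the neutrophil list 3 of 6 were lower, the same adjusted over the list alone (adjusted p = 0.00752, and 0.521 with an estimated correlation), including S100a9 at 3.67-fold and Ltf at 2.64-fold. The interferon-stimulated list was called lower (adjusted p = 0.0432, and 0.508 with an estimated correlation) with 4 of 15 lower and 1 higher, and 5 and 1 adjusted over the list alone. The call of the interferon-stimulated list was lost without KO 1 (0.0516), KO 2 (0.0838) or WT 3 (0.0755), with at least 50 counts in 3 libraries (0.103) and with 6 separate libraries (0.0558). Ifit3 was 1.60-fold lower, and its call was lost without KO 2 (FDR 0.0855). The inflammatory cytokine list had 3 tested members and was not called (adjusted p = 0.118), and its member Nos2 was 2.97-fold lower, the only call also when adjusted over the list alone. Of the B cell list 2 members and of the T and NK cell list none were tested, so neither list had a test.

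Among the other lists, ribosomal protein genes were called lower (camera adjusted p = 0.036, and 0.898 with an estimated correlation), although 2 of 31 passed and none adjusted over the list alone. The ribosomal protein list was not called without KO 2 (adjusted p = 0.3) or by fry (0.476). The insulin-like growth factor axis was not called (adjusted p = 0.35), with 5 of 15 lower and 3 higher, and 5 and 4 adjusted over the list alone. Igf1 was 2.09-fold, Igf2 1.58-fold and H19 1.57-fold lower. TGF-beta and BMP genes had 3 higher and 1 lower of 18, the same adjusted over the list alone (adjusted p = 0.81), with Bmp6 2.67-fold higher and Tgfb3 1.59-fold lower. Wnt targets and antagonists had 3 of 15 lower, the same adjusted over the list alone (adjusted p = 0.231), with Nkd1 1.99-fold lower. The m6A list had 1 of 16 members past the test, Fto, an m6A demethylase, at 1.48-fold lower, also adjusted over the list alone (adjusted p = 0.81). The Fto call was lost without KO 2 (FDR 0.151) or WT 1 (FDR 0.0732). Keratinocyte and skin genes had 1 of 10 lower, Krt5 at 1.41-fold, also adjusted over the list alone (adjusted p = 0.81), lost without KO 2 (FDR 0.18). No member of the cell cycle list (17 tested, adjusted p = 0.987) or the erythroid list (9 tested, adjusted p = 0.549) passed, over all genes or over the list alone.

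**Figure D4:**
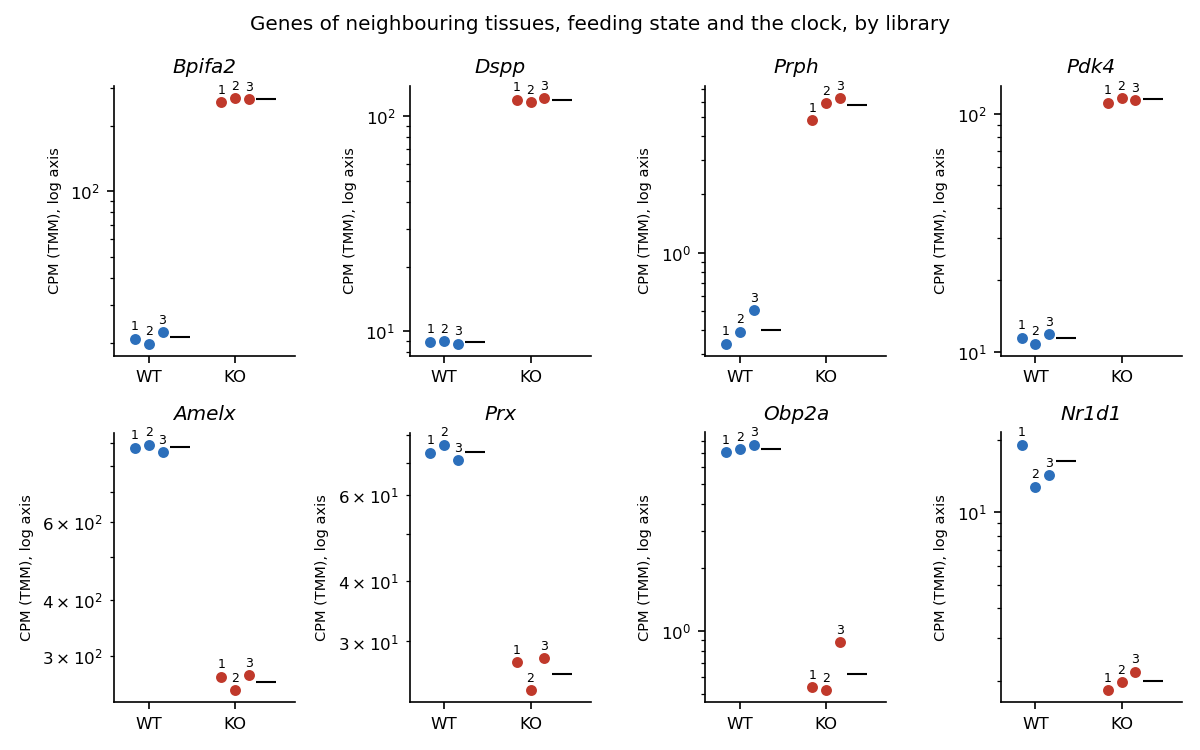
CPM (TMM-scaled, log axis) of 8 genes in each of the 6 libraries, numbered by replicate, with the mean of the 2 samples per group as a black bar. Bpifa2, Dspp, Prph and Pdk4 are higher and Amelx, Prx, Obp2a and Nr1d1 lower in every KO library than in every WT library, and Dspp, Amelx and Prx were chosen for it after their values were seen.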

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

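The 6 separate libraries of the first plan became an alternative only after seeing the data. The settings with a block for KO 2 and WT 1 and with halved counts were also chosen after seeing the data, as was the test on other splits of the libraries. The count of differing genes (2580, with 1339 higher and 1241 lower) stayed within 1.5 times in most settings, from 2092 to 3845 genes. In the setting with 3845 the 1872 lower genes, counted alone, were just over 1.5 times the 1241. The count of differing genes was 1371 with the DESeq2 Wald test (774 higher, 597 lower) and 1058 with a minimum log2 change of 1 (575 and 483), where fewer genes qualify by construction. Leaving out each library gave 1149 to 2434 genes (616 to 1348 higher, 533 to 1187 lower), and the lowest was without KO 2, which leaves KO with 1 sample that is assumed to vary like the WT samples. Leaving out WT 1 likewise left 1 WT sample and gave 2396 genes. The block for KO 2 and WT 1, whose deviations correlated (r = 0.36 across genes, which are not independent) and rose with transcript length (rho 0.278 and 0.25), gave 1973 higher and 1872 lower genes, and 2576 of the 2580 were shared. The log2 fold change itself had a rho of 0.124 with length. Same-numbered deviations correlated at -0.16, -0.24 and 0.20, so no pairing by replicate number was visible. Deviations were taken from the mean of each group, which ties these correlations to each other, so pairing is not excluded. With the replicate number as a block and 6 libraries, 2941 genes were called (1493 and 1448), Igf2bp2 was at -1.74, Fos at -1.61, Pparg at -0.76 and Nfatc1 at 0.13, and 16 lists were called. With 6 separate libraries 3452 genes were called, and the highest of the other 9 splits into 3 and 3 gave 1. The real split was 1 of 10, too few for a share under 0.05.

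The fast muscle covariate shared 1154 calls with the main result and turned the sign of 65. Under it Igf2bp2 was at -1.01, Fos at -0.60 and Pparg at -0.65, none past the threshold, and Nfatc1 at 0.74, past it. Ckm (-0.43), Arntl (-1.04), Mmp20 (-0.22), Nefm (-0.42), Usp2 (-0.0099) and Wee1 (-0.027) changed sign. Wee1, which did not pass in the main result, ranged from -0.022 to 0.26 over the left-out libraries. Of 124 other named genes that were called, 17 lost their call without KO 2, 11 in the DESeq2 Wald test and 23 under the covariate. The list's mean is set by few samples and by the groups, and the cause was not tested. The DESeq2 Wald test ended the calls of Igf2bp2 (-1.80) and Pparg (-0.75) at nearly the same fold changes. Pparg ranged from -0.90 to -0.65 over the left-out libraries and lost its call without KO 2. With an estimated correlation 0 lists were called, with fry 10 and with at least 50 counts in 3 libraries 13, against 16. The osteoclast list had an adjusted p of 0.502 with an estimated correlation and 0.0203 to 0.0515 over the left-out libraries, and the network list had 0.0515 to 0.329. The depth of 2625472 to 4899680 nuclear counts limits low genes such as Igf2bp2, Fos and Ucp1 most.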

Other observations

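The lists in this part were written after the main results had been seen, and of the tests below those on repeat libraries, on a library listed more than 1 time, on time of day and on genotype in neighbouring tissues were chosen after the values they measure were seen. Of 18 genes that fasting or glucocorticoids raise in muscle and other tissues, 15 were higher in KO and none lower, by edgeR's test at the FDR of 0.05. Fkbp5, a co-chaperone induced by glucocorticoid receptor, had 58.4 ± 0.422 CPM in KO and 8.66 ± 1.06 in WT (SD, n = 2 samples). Zbtb16 was 6.56-fold higher, and the muscle ubiquitin ligase genes Fbxo32 and Trim63 were 4.76-fold and 7.96-fold higher. Ucp3 was 8.93-fold higher, and Mt2 and Cdkn1a were 3.61-fold and 2.70-fold higher.

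Of 14 tested genes of autonomic ganglion neurons, 13 were higher in KO, and the other did not pass (FDR 0.299). Many of them are genes of neurons in general, so the list does not mark autonomic ganglion alone. Phox2a, a transcription factor of autonomic neurons, had 86 counts over the KO libraries and none in WT, 18.5-fold higher against a floor of 3 counts. Slc18a3, the vesicular acetylcholine transporter, had 168 counts in KO and none in WT. Of 10 tested genes of the enamel organ 6 were lower in KO and 1 higher. Of those looked at before the list was written, Amelx had 262 ± 13.8 CPM in KO and 883 ± 2.69 in WT, and Ambn was 4.26-fold, Odam 5.45-fold and Amtn 6.15-fold lower in KO. Of those not looked at before, Enam had 16.4 CPM in KO and 49.0 in WT (FDR 1.74e-06). Slc13a5, of the same list, was 2.65-fold higher and Mmp20 had 3.73 CPM in KO and 3.36 in WT (FDR 0.665). Dspp, the dentin gene of odontoblasts, had 118 ± 3.09 CPM in KO and 8.97 ± 0.0373 in WT. Of 10 tested nasal mucosa genes 7 were lower in KO, Omp of olfactory neurons 3.81-fold and Bpifa1 6.37-fold.

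The near-identity of KO 1 with KO 3 and of WT 2 with WT 3 was weighed first. A single library listed more than 1 time is argued against, because mitochondrial genes still differed by far more than counting noise at their depth. They differed by up to 0.145 on the log2 scale between WT 2 and WT 3 and up to 0.399 between KO 1 and KO 3. Repeat libraries of the same RNA are a candidate explanation. The higher of the pairs' median variance ratios in genes of 1000 to 5000 counts was 1.05, near the 0.978 of simulated repeats over all genes. The other pairs within a group, counted as separate samples, had ratios of 2.4 to 5.6. All of these lie below the 5.85 of simulated animals differing by 10%, so that value does not set the close pairs apart from the others. In mitochondrial genes KO 1 and KO 2, counted as separate samples, differed by at most 0.14, less than KO 1 and KO 3. WT 1 differed from WT 2 and WT 3 by up to 0.463 and 0.558, more than WT 2 from WT 3. Whether KO 2 and WT 1 came from other animals stays open, and so does pooling of tissue before extraction.

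The shifts in salivary, neuronal, enamel and nasal transcripts may come from different amounts of neighbouring tissue in the dissected joints. Of 14 ganglion markers not looked at before, 92.9% were higher in KO, and of 6 such nasal markers 50% were lower. Ganglion in the KO libraries and more nasal mucosa in the WT libraries thus stay open as sources. Of 11 further salivary markers, which duct and other epithelia also express, 45.5% rose and none fell. That lies between the limits of 25% and 50% set beforehand and decides nothing. More salivary gland in the KO libraries stays open too, since all 13 tested members of the list fixed beforehand rose. Of 4 unseen enamel markers 1 fell (25%) and 1 rose, too few to decide. An effect of Igf2bp2 loss on these tissues cannot be told apart from tissue content, since no independent animals are labelled. That 0 of the 3 KO libraries lay within the WT range of the salivary mean follows from the calls above and decides nothing. No biological explanation is favoured by these tests.

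The clock and fasting genes may reflect when and in what state the mice were killed. Of fasting and glucocorticoid genes not looked at before, 84.6% were higher in KO, as a difference in feeding or stress hormone needs. Genes that peak with Bmal1 stood 2.15 above genes that peak with Dbp in the median log2 fold change, while Per2 went against its group and Usp2, Wee1 and Arntl did not pass. Most of these are the clock genes that raised the question, so their difference does not support collection at another time of day. Both stay open, and neither separates a difference in handling from an effect of genotype on rhythm or metabolism.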
